A study of Mus musculus with 12 samples.

How the data were processed

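Single hepatocytes and liver macrophages of mice were profiled by single-cell RNA sequencing, with 10X Chromium droplets for 3 pooled libraries and with Smart-seq2 for 9 libraries. The values analysed here are the deposited annotation of each cell, with no value per gene. The hepatocyte table held 6573 cells of 9 libraries and the myeloid table held 8234 cells of 1 library, so 10 of the 12 samples had cells to analyse. The other samples, a pair of day 3 Smart-seq2 libraries, were not analysed here. Each table gave the library, the cell type name and the cluster number that the authors assigned to every cell, and the hepatocyte table also gave the platform, the batch and a position on a map.

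Reads were processed with Cell Ranger 6.0.1, cutadapt 1.14, Trimmomatic 0.36, UMI-tools, STAR 2.5.2b, HTSeq 0.6.0 and Seurat 4.0.1, per the submitters' processing notes, which also name the mouse build mm10 and give no role for any tool. Hepatocyte clusters were made on data integrated across libraries, per the file headers. The deposited map positions are UMAP coordinates, a score with no unit and no true zero, and were used here only to find the nearest cells of each cell. Integration and clustering across libraries can move cells of different libraries into a shared cluster, and a cluster taken mostly from 1 library can be a feature of that library. Filters on cells, doublet handling, UMIs and genes per cell are not given in the sources used here, and no cell was removed or added. The authors' cell type names were taken as deposited and were not checked against marker genes.

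Groups were taken from the labels. The 10X libraries each pooled cells of 2 mice on normal diet and 2 mice fed DDC for 7 days. The diet and animal of single 10X cells are not given in the sources used here, so each pool was treated as 1 sample and the planned comparison of day 7 with day 0 within a pool was not made. The planned comparison of CLO with no CLO at day 7 was made on whole pools, day 0 and day 7 together, for the same reason. Smart-seq2 cells came from Sox9-EGFP mice, 1 on normal diet and 2 fed DDC, and those of injured livers were sorted by size and GFP. The titles do not say whether the 2 mice fed DDC are per day or cover day 3 and day 7 together. Day 7 may therefore rest on 1 mouse. The 3 libraries of day 7 alone (L4, Z103 and Z104, replicates 1, 2 and 3) were set against the day 0 library (Z101). The deposited table's treatment and library set columns name DDC and 1 week for all Smart-seq2 cells, Z101 included, and the labels' day 0 was followed. The library set column also names 1 week for both 10X hepatocyte pools, whose labels give day 0 and day 7 together, and the labels were followed there too. The labels' protocol gives 2 mice per Smart-seq2 group and the title of Z101 gives 1 for normal diet, and the title was followed. The strain tag of Z104 reads 129S7 where those of the other Smart-seq2 libraries read 129S6, and Z104 was kept in the day 7 group. The 3 libraries of mixed days (L3, L5 and Z102) were left out of the day comparison, except in an alternative that counts L3 and L5 as day 7, since the day of their single cells is not given in the sources used here.

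A share is the percent of a library's cells with a given cell type or cluster. Shares carry exact Clopper-Pearson 95% intervals, differences of shares carry Newcombe intervals and ratios of shares carry Katz log intervals. A count of 0 cells was given the limit that 3 cells would set, or its exact upper bound where so stated. All of these cover counting error only and leave out the spread between animals. Day 7 Smart-seq2 shares are given as mean ± SD over libraries. Each 10X arm was 1 library, so no test between the pools was possible. Between day 7 and day 0 the design fixed before the data were examined had no test. None was run on 3 libraries of at most 2 mice against 1 library. The design planned a permutation test of day 3 against day 7 libraries. That test was not made, since the day 3 libraries had no annotated cells. No p-value is given. The same design asked for every cell type and cluster holding at least 1% of either arm to be named, with smaller clusters summed. No gene is named because no value per gene was used.

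Precision follows the number of cells, from 4800 in the 10X pool without CLO and 1446 in the CLO pool to between 26 and 82 in a Smart-seq2 library. Alternatives changed the denominator, the libraries included, the weighting of libraries, the batch, the clusters included and the cell type name. The name was replaced by the commonest name among the 30 nearest cells on the map, which need not be a majority. Ties went to the type listed first, and NormalHeps headed the list. Mixing of the pools within a cell type was measured over the 15 nearest cells of that type. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.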

Results

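Hepatocytes of mice on normal diet and of mice fed DDC, a diet that injures the liver and blocks bile flow, were annotated at the level of single cells together with F4/80-enriched liver macrophages. The hepatocyte data comprised 4800 cells of a 10X pool, 1446 cells of a 10X pool with CLO treatment, which the labels do not spell out, and 327 Smart-seq2 cells of 7 libraries. The authors sorted these cells into 25 clusters under 8 cell type names. NormalHeps were normal hepatocytes, InjuredHeps1 and InjuredHeps2 were injured hepatocytes, and ProliHeps carried a name for proliferating hepatocytes. PreLPLCs, LPLCs, PostLPLCs1 and PostLPLCs2 were named as stages around the LPLC, a hepatocyte-derived progenitor-like cell that switches on Sox9, a transcription factor of bile duct cells. The myeloid data comprised 8234 cells in 12 clusters under 6 names. UMIs and genes per cell are not given in the sources used here, so precision is stated from numbers of cells alone.

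The first comparison asked how the hepatocyte types differed between the 10X pools with and without CLO. InjuredHeps1 made up 20.1% (95% interval 19.0 to 21.3) of the pool without CLO and 1.24% (0.739 to 1.96) of the CLO pool, a share 16.2 times lower (10.2 to 25.6). PostLPLCs1 went the other way, with 11.5% (10.6 to 12.4) without CLO and 33.2% (30.8 to 35.7) with CLO, a ratio of 2.89 (2.59 to 3.21). ProliHeps were also higher with CLO, at 14.7% (12.9 to 16.6) against 4.42% (3.85 to 5.04). PostLPLCs2 were lower with CLO, at 3.87% (2.94 to 5.0) against 16.2% (15.2 to 17.3). NormalHeps took nearly the same share of both pools, 24.9% (23.7 to 26.1) without CLO and 25.4% (23.2 to 27.7) with CLO.

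LPLCs themselves made up 4.10% (3.56 to 4.70) of the pool without CLO and 7.68% (6.36 to 9.17) of the CLO pool, a ratio of 1.87 (1.49 to 2.34). PreLPLCs differed by 0.438 percentage points (-0.507 to 1.57), within counting error. InjuredHeps2 were lower with CLO, at 10.7% (9.17 to 12.4) against 16% (15 to 17). The 4 LPLC stages together held 34.6% (33.3 to 36) of the pool without CLO and 48.0% (45.4 to 50.6) of the CLO pool, while both injured types together held 36.1% (34.7 to 37.5) and 12.0% (10.3 to 13.7). The balance between PostLPLCs1 and PostLPLCs2 was reversed, with 0.710 PostLPLCs1 cells per PostLPLCs2 cell without CLO and 8.57 with CLO. Of all InjuredHeps1 cells in the hepatocyte data, 965 of 998 (96.7%) came from the pool without CLO, as did 778 of 850 PostLPLCs2 cells (91.5%) and 73.0% of all hepatocyte cells.

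**Figure D1:**
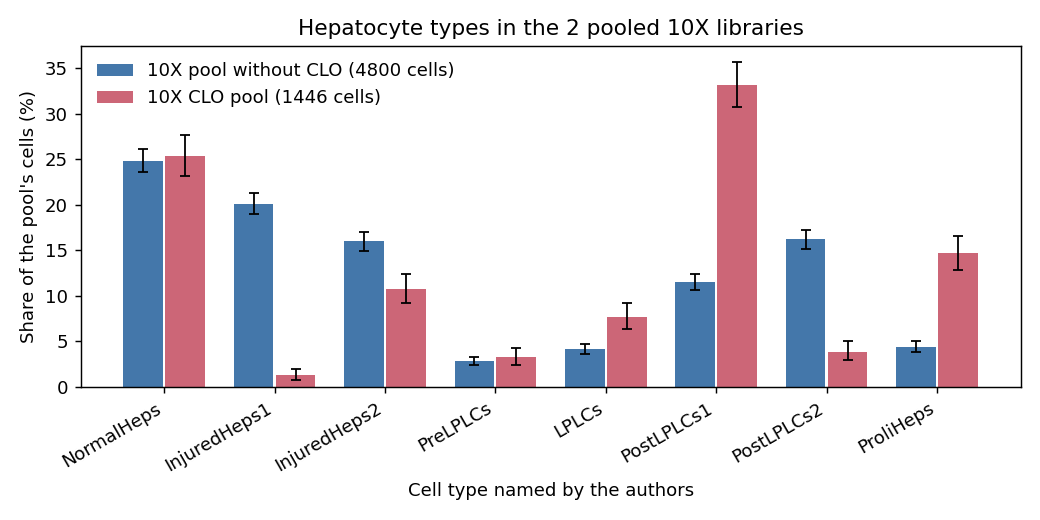
Share of each hepatocyte type in percent of all cells of a pool, for the 10X pool without CLO and the 10X CLO pool, with bars from 0 and exact 95% intervals for counting error. InjuredHeps1 stand at 20.1% without and 1.24% with CLO, and PostLPLCs1 at 11.5% and 33.2%.

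At the level of clusters, 12 of 25 held a higher share of the CLO pool, 12 a lower share, and cluster 13, the PreLPLCs, could not be separated from no difference. All 4 InjuredHeps1 clusters were lower with CLO. Cluster 3 went from 9.79% to 0.553%, cluster 9 from 6.63% to 0.207% (3 cells, ratio 0.0313, 0.0101 to 0.0975), cluster 17 from 2.21% to 0.415% and cluster 19 from 1.48% to 0.0692% (1 cell, ratio 0.0468, 0.00650 to 0.336). All 4 PostLPLCs1 clusters were higher with CLO, by 2.67 times in cluster 4, 3.20 times in cluster 6, 2.65 times in cluster 10 and 3.76 times in cluster 20. Both ProliHeps clusters were higher, cluster 8 by 2.74 times (2.22 to 3.38) and cluster 18 by 6.26 times (4.17 to 9.39). The single LPLC cluster, 7, has the values given for LPLCs.

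The near-equal NormalHeps share was made of clusters that went both ways. Cluster 0 went from 13.2% without CLO to 3.80% with CLO, cluster 14 from 3.31% to 1.04%, cluster 22 from 1.25% to 0.346% and cluster 23 from 1.06% to 0.138% (2 cells, ratio 0.130, 0.0317 to 0.534). Clusters 11, 12 and 15 were higher with CLO, at 6.98% against 1.58%, 8.71% against 1.5% and 4.29% against 2.04%. InjuredHeps2 split as well, with cluster 2 at 10.6% without and 3.67% with CLO and cluster 5 at 5.35% and 7.05%. Among PostLPLCs2, cluster 1 went from 12.9% to 1.11% and cluster 16 from 2.58% to 0.830%, while cluster 21 went from 0.729% to 1.94%. The 1 cluster under 1% in both pools, also NormalHeps, held 0.917% without CLO and 0.0692% with CLO.

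**Figure D2:**
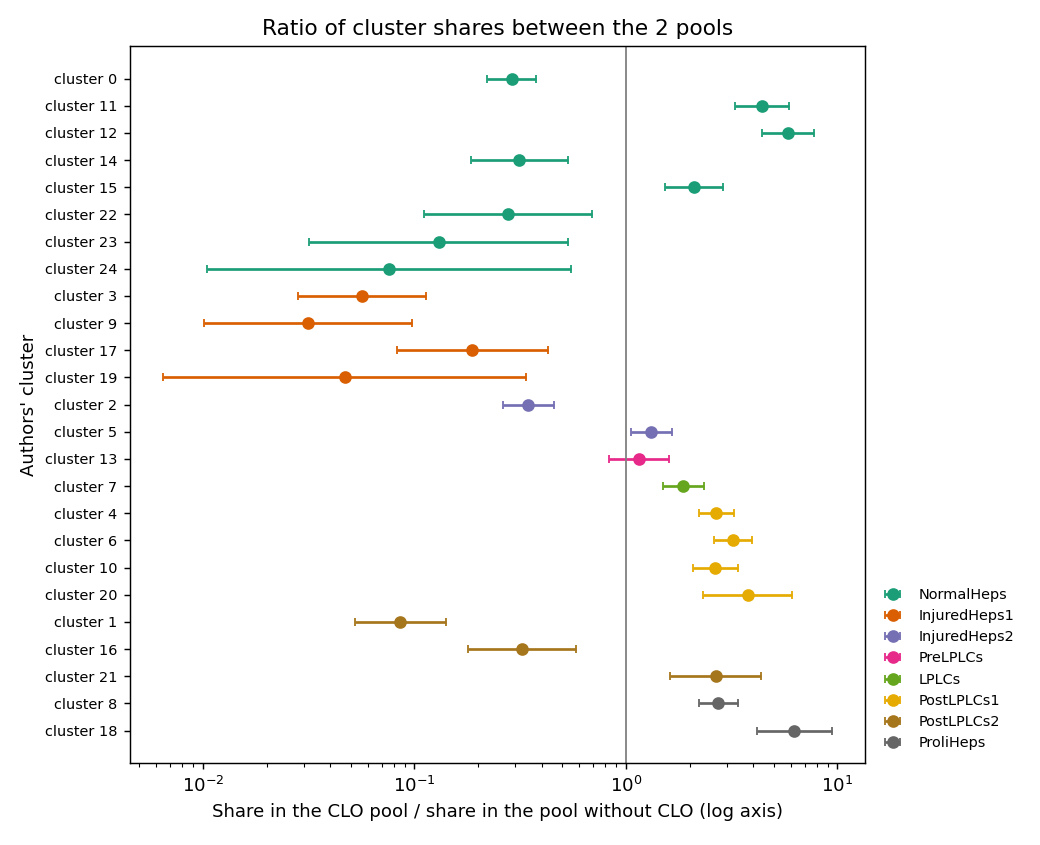
Ratio of the share in the 10X CLO pool to the share in the 10X pool without CLO for each of the 25 hepatocyte clusters, on a log axis, with 95% intervals for counting error and colours for cell types. The 4 InjuredHeps1 clusters lie below 1, the 4 PostLPLCs1 clusters lie above 1, and NormalHeps clusters lie on both sides.

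The cells of the pools were unevenly mixed within types on the authors' map. CLO cells were 23.5% of the NormalHeps of both pools, but 62.4% of the 15 nearest NormalHeps of a CLO cell and 11.8% of those of a cell without CLO. In PostLPLCs2, CLO cells were 6.71% of the type and 48.8% of the neighbours of a CLO cell, in InjuredHeps2 16.8% and 42.7%, in InjuredHeps1 1.83% and 8.89%, and in ProliHeps 50% and 77.8%. In PostLPLCs1 the same numbers were 46.5% and 58.3%, in LPLCs 36% and 42.3%, and in PreLPLCs 25.8% and 30.2%.

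Each arm was 1 pool and 1 batch of 2 mice per diet, so no test was possible and the batch and the CLO treatment cannot be told apart. Shares of a whole depend on each other and on single clusters, and a cluster left out below also left the denominator. Among cells other than InjuredHeps1, the NormalHeps ratio was 0.825 (0.747 to 0.912). With cluster 2 left out the InjuredHeps2 ratio became 1.22 (0.980 to 1.52), with cluster 1 left out the PostLPLCs2 ratio became 0.736 (0.523 to 1.03), with cluster 0 left out the NormalHeps ratio became 1.67 (1.47 to 1.89), and with cluster 8 left out the ProliHeps ratio became 6.71 (4.47 to 10.1).

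The second comparison set Smart-seq2 libraries of day 7 of DDC against the library of day 0, in mice whose GFP marks cells that use Sox9. A sort by size and GFP is stated for injured livers only, so the differences below cannot tell day from sort. The day 0 library is day 0 by its label, while the cell table gives all Smart-seq2 cells a 1-week DDC set name. NormalHeps made up 65.1% (49.1 to 79.0) of the 43 cells at day 0 and 2.84% ± 4.91 (SD, n = 3) at day 7. PostLPLCs1 were the main type at day 7, at 42.4% ± 3.66 (SD, n = 3), against 4.65% (0.568 to 15.8) at day 0. LPLCs followed at 24.2% ± 7.72 (SD, n = 3), against 0 of 43 cells at day 0, which allows a share of up to 6.98%. ProliHeps reached 10.7% ± 6.22 (SD, n = 3) and were also at 0 of 43 cells at day 0.

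Library by library, LPLCs were 15.9%, 25.5% and 31.1% in day 7 replicates 1, 2 and 3, all above the day 0 limit. PostLPLCs1 were 40.2%, 40.4% and 46.7%, and NormalHeps were 0%, 8.51% and 0%. ProliHeps were 3.66%, 12.8% and 15.6%, so replicate 1 lay under the day 0 limit. The 4 LPLC stages together held 70.7%, 72.3% and 80.0% of the day 7 libraries and 14.0% (5.30 to 27.9) of the day 0 library.

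InjuredHeps1 made up 4.12% ± 0.410 (SD, n = 3) at day 7 and 0 of 43 cells at day 0, a difference not detectable with this number of cells. InjuredHeps2 were 22.0%, 2.13% and 0% in the 3 day 7 libraries and 20.9% (10.0 to 36) at day 0. PreLPLCs were 9.76%, 0% and 2.22% at day 7 and 0 of 43 cells at day 0. PostLPLCs2 were 3.75% ± 3.34 (SD, n = 3) at day 7 and 9.30% (2.59 to 22.1) at day 0, within counting error of each other.

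**Figure D3:**
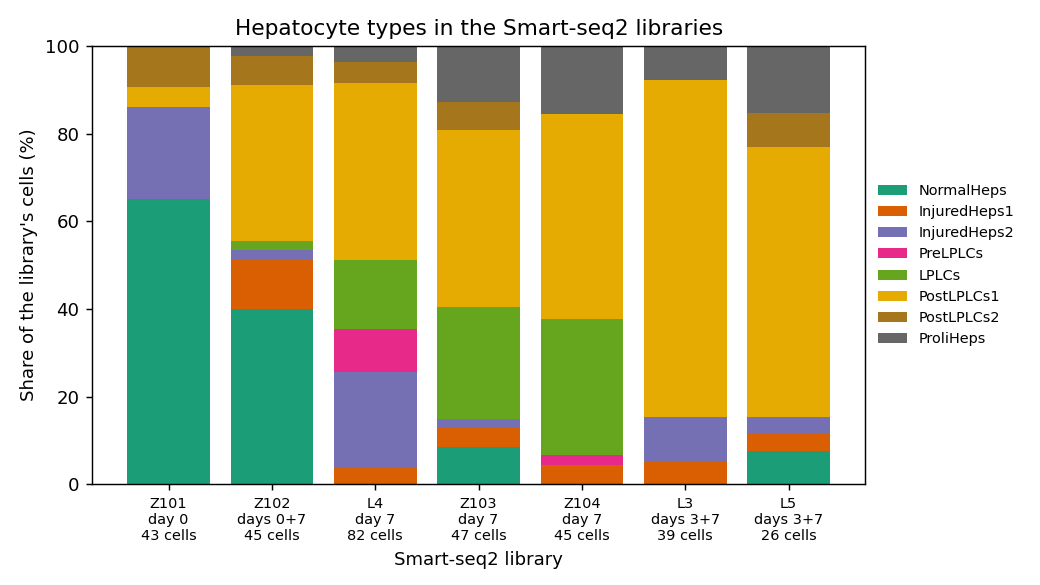
Share of each hepatocyte type in percent of a library's cells, 1 stacked bar for each of the 7 Smart-seq2 libraries from 0 to 100, with the day or days of DDC and the number of cells under each bar and no error drawn. NormalHeps lead in the day 0 library with 65.1%, and PostLPLCs1 lead in the 3 day 7 libraries with a mean of 42.4%, while the 3 libraries of mixed days are shown for their values only. Cells of injured livers were sorted by size and GFP, so day and sort cannot be told apart.

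Within batch 1, which held the day 0 library and day 7 replicates 2 and 3, the day 7 means were 4.26% for NormalHeps, 28.3% for LPLCs, 43.5% for PostLPLCs1 and 14.2% for ProliHeps. Batch 2 held only day 7 replicate 1 among the libraries compared, where InjuredHeps2 were 22.0% against a batch 1 mean of 1.06%, so that this type and PreLPLCs rested on that library. Without it the day 7 minus day 0 difference went from 3.99 to 1.11 percentage points for PreLPLCs and from -12.9 to -19.9 for InjuredHeps2, and without replicate 3 that of PostLPLCs2 went from -5.55 to -3.67. Day 7 cells of injured livers were sorted by size and GFP, which can set the shares, including that of LPLCs, which switch on Sox9. That sort is stated for injured livers only, so day and sort cannot be told apart. The 3 libraries came from at most 2 mice, which the labels do not tie to libraries. The SD therefore measures spread between libraries, of which replicate 3 carries another strain tag than the others. When each cell took the commonest name among its 30 nearest cells on the map, some day 7 minus day 0 differences changed. That of InjuredHeps2 went from -12.9 to 3.27 percentage points and that of PostLPLCs2 from -5.55 to -0.293. Counting the libraries of mixed day 3 and day 7 as day 7 lowered the LPLC difference from 24.2 to 14.5 points.

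The myeloid pool joined F4/80-enriched cells of normal and DDC-injured livers. Kupffer cells, the resident macrophages of the liver, were the main population with 4627 of 8234 cells (56.2%, 55.1 to 57.3). DDC KPCs, the Kupffer cells that the authors named for the diet, made up 50.6% (49.5 to 51.7) in 5 clusters, and Normal KPCs made up 5.56% (5.08 to 6.08) in 1 cluster, a ratio of 9.10 DDC KPCs per Normal KPC. Monocytes made up 26.2% (25.3 to 27.2) in 3 clusters. MoMFs, the monocyte-derived macrophages, made up 13.4% (12.7 to 14.2).

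Of the 5 DDC KPC clusters, cluster 0 held 17.4% of the pool, cluster 1 held 15%, cluster 5 8.65%, cluster 7 5.22% and cluster 8 4.36%. The monocyte clusters 3, 4 and 10 held 12.3%, 11.3% and 2.60%. There were 1.95 monocytes per MoMF. LSECs, the endothelial cells that line the liver sinusoids, made up 2.60% (2.27 to 2.97), and a joint group of T cells and pDCs made up 1.53% (1.28 to 1.82).

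**Figure D4:**
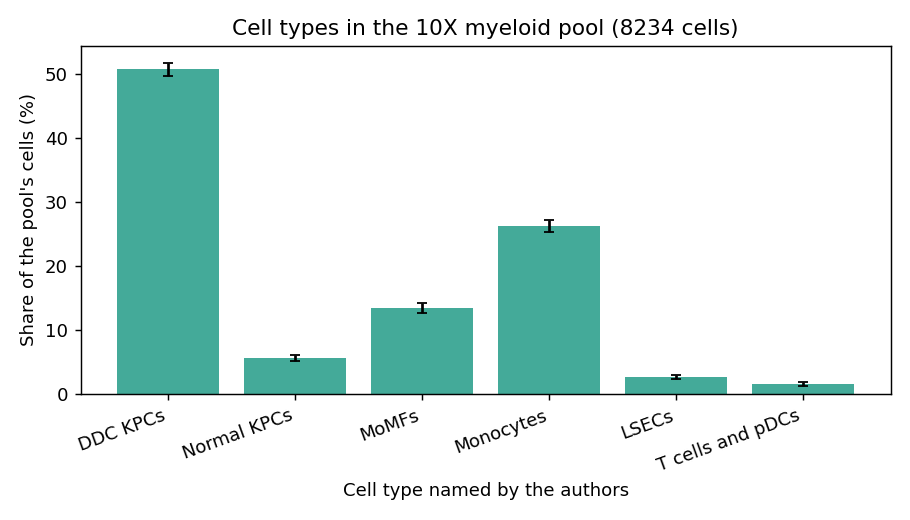
Share of each myeloid cell type in percent of the 8234 cells of the pool, with bars from 0 and exact 95% intervals for counting error. DDC KPCs lead with 50.6%, and Normal KPCs stand at 5.56%.

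The pool held 2 mice per diet in 1 library, and the diet of single cells is not given in the sources used here, so the myeloid types were not compared between day 0 and day 7. The labels state 10210 pooled cells, the 8234 annotated cells are 80.6% of that number, and the F4/80 enrichment sets which cells could enter.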

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

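All tests in this part were chosen after the results were seen. The 3 Smart-seq2 libraries of mixed days, which were left out of the day comparison, stood out because their share of PostLPLCs1 lay above that of the day 0 library, 4.65% (95% interval 0.568 to 15.8). It was 76.9% (60.7 to 88.9) in library L3 and 61.5% (40.6 to 79.8) in library L5, both of mixed day 3 and day 7. It was 35.6% (21.9 to 51.2) in library Z102, of mixed day 0 and day 7.

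In library Z102, PostLPLCs1 and NormalHeps stood in separate ranges of the cell barcode number, while InjuredHeps1 ran across both, from 14 to 49. All 16 PostLPLCs1 cells had numbers from 1 to 25 and all 18 NormalHeps cells had numbers from 27 to 50, with an area under the curve of 0.909 (0.811 to 1) for NormalHeps against other cells. If the number itself shifted the name, the day 0 library would show the same order, and there the area was 0.440 (0.257 to 0.624). This argues against it for NormalHeps against other cells in that library, but only 2 of those 15 other cells were PostLPLCs1. One diet day per barcode range remains a candidate explanation and is a hypothesis that was not tested, since the day of each cell is not given in the sources used here. Day 7 replicate 2 also had its 4 NormalHeps at 27 to 49, with an area of 0.826 (0.569 to 1). By its label this library held day 7 alone, so mixed days cannot give that order. That order rests on 4 cells. PostLPLCs1 ran from 1 to 48 there and from 2 to 45 in Z104, a day 7 library of the same batch. NormalHeps ran from 1 to 49 in the day 0 library. These ranges argue against a number that alone holds PostLPLCs1 to 1 to 25 or NormalHeps to 27 to 50. The 2 PostLPLCs1 of the day 0 library, at 16 and 25, do not. A weaker effect of the number is therefore not excluded.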

How the results depend on the processing

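Of the alternatives, only the myeloid denominator and leaving out each day 7 library were planned; the others were chosen after seeing the data. Of 14 alternative CLO ratios 6 stayed within the interval of the reported value, 7 moved and 1 reversed; of 16 day differences 10 stayed within 1 SD and 6 moved, that of InjuredHeps2 with a change of sign. These counts leave out 14 ratios and 4 myeloid shares with another denominator, which multiplies all types by 1 factor, and 40 differences from fewer or reweighted day 7 libraries, which cannot leave 1 SD with 3 libraries. Leaving out each day 7 library gave 1.11 to 5.99 points for PreLPLCs, -19.9 to -8.89 for InjuredHeps2 and -6.86 to -3.67 for PostLPLCs2, with 1.11 and -19.9 without replicate 1 and -3.67 without replicate 3. For the other types it gave -65.1 to -60.9 for NormalHeps, 3.96 to 4.35 for InjuredHeps1, 20.7 to 28.3 for LPLCs, 35.7 to 38.9 for PostLPLCs1 and 8.21 to 14.2 for ProliHeps. Without InjuredHeps1 in the denominator the CLO ratio was 0.825 (0.747 to 0.912) for NormalHeps, 0.543 for InjuredHeps2, 2.34 for PostLPLCs1 and 2.69 for ProliHeps, a result of the smaller denominator. Without the largest cluster of the type, which also left the denominator, it was 1.67 for NormalHeps, 3.29 for PostLPLCs1, 0.736 for PostLPLCs2 and 6.71 for ProliHeps. For InjuredHeps2 it crossed 1 to 1.22 (0.980 to 1.52), counted as reversed although its interval includes 1. Clusters of a type differed, and the denominator changed as well. With names from the 30 nearest cells it was 0.529 for InjuredHeps2, 2.76 for LPLCs and 2.52 for PostLPLCs1; the cause was not tested. With the same names the day difference was -84.2 points for NormalHeps, 3.00 for InjuredHeps1, 3.27 for InjuredHeps2 and -0.293 for PostLPLCs2. In the day 0 library this naming took NormalHeps from 28 to 37 of 43 cells, InjuredHeps2 from 9 to 2 and PostLPLCs2 from 4 to 1. With mixed day 3 and day 7 libraries as day 7 the difference was 14.5 for LPLCs and 48.5 for PostLPLCs1. Among macrophages and monocytes alone, DDC KPCs were 52.8% and monocytes 27.4%. Alternatives on UMIs, genes, mitochondrial share or depth, and both platforms together, were not run; the other cluster column was identical and all hepatocyte names are one lineage, so neither gave another value. No paired analysis was possible because the labels tie no library of one group to a library of another.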

Other observations

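All tests in this part were chosen after the results were seen. Libraries L3 and L5, of mixed day 3 and day 7, held no LPLCs, at 0 of 39 and 0 of 26 cells, which allow shares of up to 7.69% and 11.5%. The 3 libraries of day 7 alone held 15.9% to 31.1% LPLCs. The day of single L3 and L5 cells is not given, and some or all may be day 7. Their lack of LPLCs can therefore not be tied to day 3. The cells of L3 had barcode numbers from 49 to 96 and those of L5 from 57 to 95, while those of L4, a day 7 library of the same batch, ran from 1 to 96. In Z102, of mixed day 0 and day 7, InjuredHeps1 made up 11.1% (3.71 to 24.1) of the cells and LPLCs 2.22%.

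With NormalHeps left out, the 3 day 7 Smart-seq2 libraries, which had no CLO, were nearer in composition to the 10X CLO pool than to the 10X pool without CLO. The sum of absolute differences in share, divided by 2, was 20.5, 22.4 and 25.8 points to the CLO pool for replicates 1, 2 and 3, and 42.0, 59.4 and 66.7 points to the pool without CLO. These libraries held day 7 cells sorted by size and GFP, from another strain and platform than the pools, which also held day 0 cells. The distances therefore cannot tell CLO from these differences. Among Kupffer cells of the myeloid pool, Normal KPCs were 9.90% (9.05 to 10.8), in a pool of 2 mice per diet.

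InjuredHeps1 were lower and PostLPLCs1 higher in the CLO pool. With equal shares within each diet in both pools, a different mix of day 0 and day 7 cells could give this only if about 93.8% of the CLO pool or more came from one diet (90.2% at the upper bound of the InjuredHeps1 ratio). At that bound day 7 would need at least 14.8% NormalHeps, or day 0 at least 23.2% PostLPLCs1. By exact upper bounds, day 7 replicates 1 and 3 allow up to 4.40% and 7.87% NormalHeps, but replicate 2 allows 20.4%. The day 0 library allows up to 15.8% PostLPLCs1. A CLO pool mostly of day 7 would also need at least 20.1% InjuredHeps1 at day 0, where the exact bound of the day 0 library is 8.22%. NormalHeps shares of the pools differed by 0.505 points (-2.00 to 3.11), against a day 7 minus day 0 difference of -62.3 points in Smart-seq2. The near-equal NormalHeps share joined clusters that went both ways, so it need not mean the same cells in both pools. If the Smart-seq2 shares held in the pools, the InjuredHeps1 and NormalHeps values would go against a different mix. The Smart-seq2 libraries differ from the pools in strain, sort and platform, so the mix stays open. The 10X library or its batch may also be the source. Day 7 Smart-seq2 libraries without CLO held 4.12% InjuredHeps1 on average, below the 20.1% of the pool without CLO. They also differ from that pool in strain, sort and platform and hold no day 0 cells, so this value cannot show a batch effect. Each pool was 1 batch, so batch and CLO cannot be told apart, and an effect of CLO stays open as well.

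The day 0 library held 15 cells with names other than NormalHeps, 9 of them InjuredHeps2. By the authors' names, an admixture of day 7 cells as seen in the day 7 libraries is unlikely as the source of all of them. InjuredHeps2 were 60% (32.3 to 83.7) of these cells and 22.0% (13.6 to 32.5), 2.33% and 0% of the same set in the day 7 libraries. The day 7 libraries were sorted by size and GFP, so admixed day 7 cells of another make-up are not covered. Cells at the border of the normal hepatocytes on the map are a candidate explanation. For 9 of the 15 (60%), NormalHeps was the commonest name among the 30 nearest cells. In the day 7 libraries this held for 0 of 99 cells of the same names, but 73 of those were PostLPLCs1. By name it held for 7 of 9 against 0 of 19 InjuredHeps2, 2 of 4 against 0 of 7 PostLPLCs2 and 0 of 2 against 0 of 73 PostLPLCs1. For the 6 cells not NormalHeps by their neighbours admixture stays open, with 2 InjuredHeps2 (33.3%, 4.33 to 77.7) against 19.8%, 4.44% and 0% in the day 7 libraries named in the same way. Injury in the normal mouse or from cell isolation was not tested.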
